A study of Mus musculus with 16 samples.

How the data were processed

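RNA of cells stained for CD45 and CD11b, sorted from the cortex and labelled as microglia, was sequenced in 16 libraries from C57BL/6 mice: 4 Sham, 4 MCAO, 4 MCAO+Ctrl-exos and 4 MCAO+AS-exos. Groups were taken from the sample titles. Whether each library is a separate mouse is not given in the sources used here, and tests treat the libraries as independent. Per the labels, RNA was made into amplified cDNA and transposon-based libraries that were circularized before sequencing. Processed tables alone were used here; raw reads were not used here. The labels name HISAT2, Bowtie2 and RSEM 1.3.1 and the mouse genome build GRCm39.p6, without giving the role of each tool, the annotation or any filter. The unit of the deposited values is FPKM, fragments scaled by transcript length and by the fragments of the library. It was inferred from the naming of RSEM and from the totals, which differed between libraries; TPM of a subset of genes is not excluded. Weighted by transcript length, the values summed to 84.6 to 92.6% of what full FPKM tables would give. The files hold no counts, so the depth of each library is unknown and no counting error was computed. The table of 13982 genes by symbol and the 16 files of single libraries held identical values, to 2 decimals, and 134 genes were at 0 in all libraries. Mitochondrially encoded genes were not analysed here.

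Values were taken as log2(FPKM + 1). The 10846 genes with at least 1 FPKM in at least 4 libraries were tested, and 3136 were not. Each comparison was a contrast in 1 model of 4 group means over all 16 libraries, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust). Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Standard errors are those of the moderated fit, and FPKM are given as mean ± SD of 4 libraries. A set of 33 gene lists of processes and cell types was written before the data were examined, and the 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members of each list were also adjusted over the list alone. For the other 7 lists (T and NK cell, B cell, neuron, astrocyte, oligodendrocyte, endothelial and mural, and erythroid markers) levels alone are given.

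Before the data were examined, genes to be named were fixed by a rule. It takes, per comparison and direction, the 10 largest fold changes among genes with adjusted p below 0.05, an average level in the upper 50% of tested genes and no overlap between the 4 and 4 values. It also takes up to 4 members of each list with the smallest p, and a list of focus genes on ferroptosis, inflammation and microglia. Predicted gene models were left out, and the single results of some genes are not reported here. Where fewer than 3 genes passed in a direction, the 6 with the smallest p would have been named, and this was not needed. Alternatives fixed before the data were examined were limma without trend, quantile normalization, no filter, a minimum of 5 FPKM, a pseudocount of 0.1, a replicate block, quality weights per library, a fit of only the 8 libraries compared, a fold change of 2 beside the threshold, estimated correlation, fry, Spearman's correlation, and leaving out each library in turn. Replicate numbers carried no pairing: across comparisons, residuals of libraries with equal numbers correlated at -0.148 to 0.0923. Added after the data were seen were scaling of totals, removal of trends in transcript length and GC content from each library, that removal with quantile normalization, and leaving out MCAO+AS-exos replicate 4 with MCAO+Ctrl-exos replicate 1. Transcript lengths and GC content came from the GENCODE M21 annotation of GRCm38, another build than the authors', and were matched by symbol for 13626 genes; no coordinates were used.

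The procedure was tested on simulated data with 200 of 10846 genes changed in each comparison. Genes were drawn independently, each with 1 residual SD for all 16 libraries. Of 100 genes with a log2 fold change of 1, 10 to 15 were recovered per comparison, and of 100 with a log2 fold change of 2, 59 to 67. Of the calls, 1.39 to 9.41% were false. The simulation left out the correlation between genes and differences in spread between groups or libraries. Its rates, and its list test below, need not hold for the real comparisons. A list shifted in simulation, iron handling, had a camera adjusted p of 1.41e-35, beside 2 other lists that were called. Which 2 lists these were was not recorded. Iron handling shares 5 genes each with the ferroptosis-promoting and the ferroptosis-protecting lists. With NRF2 targets and the neutrophil markers it shares 1 each. Whether the 2 calls were false is therefore not known. A simulated trend in length gave 194 calls before removal and 0 after it. Each count was compared with the 35 splits of its 8 libraries into 4 and 4. For the pair of exosome comparisons that share the MCAO libraries, unchanged groups were simulated 20 times. The MCAO group shared by both was simulated too, and genes were drawn independently. Values of single libraries were tested with Dixon's test within each group of 4 at its 95% level.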

Results

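Gene expression was measured by RNA sequencing in CD45 and CD11b stained cells, labelled as microglia, that were sorted from the cortex of C57BL/6 mice in 4 groups of 4 libraries each. MCAO is occlusion of the middle cerebral artery, a model of ischemic stroke, and Sham mice had no occlusion. The MCAO+Ctrl-exos and MCAO+AS-exos mice also received 150 µg of plasma exosomes into the tail vein at intervals of 3 days, starting with the surgery. The exosomes came from Apoe knockout mice on a normal or a western diet, the latter fed for 12 weeks to establish atherosclerosis. The labels do not spell out which diet belongs to which code. The time between surgery and sorting is not given in the sources used here. The table holds 13982 genes. Its values, read as FPKM, summed to between 758283 and 983648 per library, and 8813 to 10003 genes reached 1 FPKM. The sequencing depth is unknown, so no counting error can be given. A total of 10846 genes reached 1 FPKM in at least 4 libraries and were tested.

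Sham libraries correlated across genes with each other at r = 0.868 to 0.915 and with MCAO libraries at r = 0.659 to 0.715; genes are not independent replicates. The first principal component held 50.6% of the variance and separated Sham from every MCAO library. The second held 10.9% and placed MCAO+AS-exos replicates 1 to 3 at scores of -68.1 to -57.4, apart from replicate 4 at 13.8. Replicates 1 to 3 of MCAO+AS-exos correlated with each other at r = 0.979 to 0.985, above any other pair within a group. Replicate 4 correlated with them at a mean r of 0.915, and with the MCAO and MCAO+Ctrl-exos libraries at 0.922 and 0.928.

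**Figure D1:**
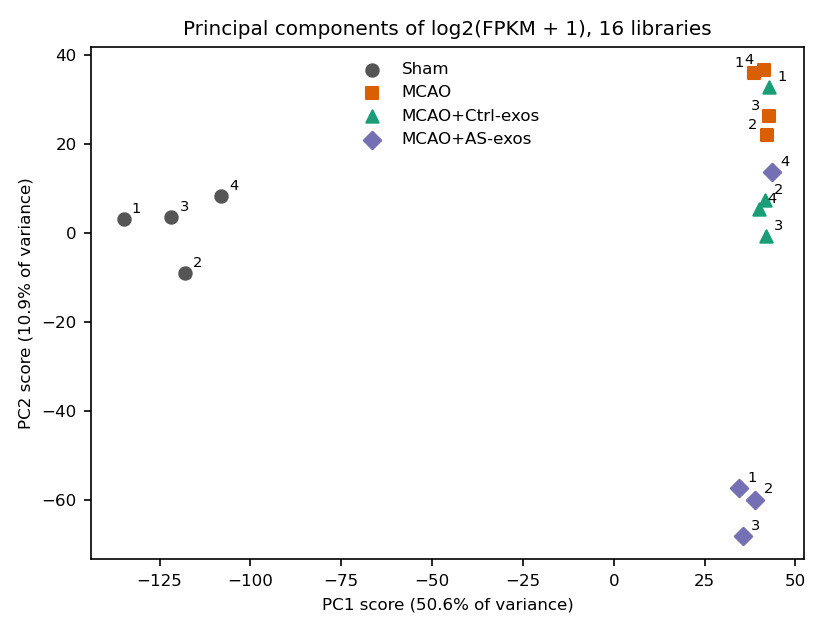
Scores of the 16 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis; numbers beside the points are replicates. MCAO+AS-exos replicates 1 to 3 lie at -68.1 to -57.4 on the second axis and replicate 4 at 13.8.

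The comparison of MCAO with Sham asks what the stroke surgery changed in the sorted cells. Genes of resting microglia were far lower after MCAO: P2ry12, the gene of a purinergic receptor of surveying microglia, fell from 4214 ± 918 to 47.7 ± 4.01 FPKM (mean ± SD, n = 4 per group). Tmem119 fell from 457 ± 223 to 28.6 ± 17.8 FPKM, and the gene of the fractalkine receptor, Cx3cr1, from 994 ± 240.4 to 51.1 ± 21.0 FPKM. Genes of activated and lipid-laden phagocytes were far higher: Spp1, which encodes osteopontin, rose from 6.47 ± 3.30 to 8002 ± 4752 FPKM. The lipid carrier gene Apoe rose from 129 ± 52.5 to 11862 ± 1872 FPKM, and Lgals3, which encodes galectin-3, from 1.58 ± 1.10 to 1518 ± 179 FPKM. Arg1, which encodes arginase 1, rose from 1.12 ± 0.527 to 1238 ± 355 FPKM. Of 10846 genes, 4254 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 2654 higher and 1600 lower. The median log2 fold change of all genes was 0.25. Quantile normalization brought that median to -0.03 and called 2084 genes higher and 2164 lower, so changes here are read against that shift. The values of the groups did not overlap for 3669 genes (33.8%), against a mean of 2.86% of genes by chance (2 of 70 arrangements of 4 against 4). Genes are not independent, so the share in a single split can lie away from that mean, and its spread was not computed.

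Among abundant genes without overlap, by the naming rule, the largest rises in log2 fold change (± SE) were those of Spp1 (9.97 ± 0.37), S100a8 (9.81 ± 0.43), Fabp5 (9.69 ± 0.26), S100a6 (9.44 ± 0.26), Wfdc17 (9.43 ± 0.39), H2-Aa (9.30 ± 0.30), Lgals3 (9.28 ± 0.24), Arg1 (9.17 ± 0.34), Vim (8.97 ± 0.33) and S100a4 (8.94 ± 0.59). S100a8 encodes a calprotectin subunit abundant in neutrophils and monocytes, Fabp5 a fatty acid binding protein, H2-Aa an MHC class II chain and Vim the intermediate filament vimentin. The largest falls were those of Siglech (-9.55 ± 0.43), Gpr34 (-7.64 ± 0.48), Crybb1 (-7.42 ± 0.77), Sparc (-6.88 ± 0.87), P2ry12 (-6.41 ± 0.31), Il1a (-6.33 ± 0.56), Cst3 (-5.85 ± 0.22), Cd81 (-5.59 ± 0.53), Hpgd (-5.57 ± 0.48) and Ecscr (-5.38 ± 0.70). Their adjusted p ranged from 3.63e-14 to 4.62e-06. Cst3, which encodes the protease inhibitor cystatin C, was the most abundant transcript of each Sham library and fell from 124973 ± 9600.0 to 2213 ± 530.4 FPKM.

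All 25 homeostatic microglia genes changed: 24 fell and 1 rose (1 up and 24 down adjusted over the list alone), with a median of -4.17 (camera adjusted p = 5.83e-25; adjusted p = 0.00103 with an estimated correlation). Sall1, a transcription factor gene of microglial identity, was among those that fell (-6.35 ± 0.32). Of the disease-associated microglia genes 20 of 27 rose, 4 fell and 3 did not pass (21 up and 4 down adjusted over the list alone; camera adjusted p = 4.97e-08; adjusted p = 0.0118 with an estimated correlation). Gpnmb (7.88 ± 0.22) and the receptor gene Lilrb4a (8.51 ± 0.29) rose with Lgals3 and Fabp5. Of the genes of lipid export and storage 19 of 23 rose, 1 fell and 3 did not pass (20 up and 1 down adjusted over the list alone; camera adjusted p = 7.27e-13; adjusted p = 7.09e-05 with an estimated correlation), among them the lipid droplet gene Plin2 (7.55 ± 0.24) and Apoc2 (8.68 ± 0.31). Of the alternative activation genes 11 of 16 rose, 1 fell and 4 did not pass (11 up and 1 down adjusted over the list alone; camera adjusted p = 2.17e-04; adjusted p = 0.00697 with an estimated correlation), including Msr1 (6.40 ± 0.27), Chil3 (8.75 ± 0.41) and the mannose receptor gene Mrc1 (4.32 ± 0.35).

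Markers of other myeloid cells that share CD45 and CD11b were higher together with these groups. Of the monocyte markers 15 of 16 rose, 0 fell and 1 did not pass (15 up and 0 down adjusted over the list alone; camera adjusted p = 1.76e-14; adjusted p = 2.66e-04 with an estimated correlation). Among them were Fn1 (7.51 ± 0.25), F13a1 (7.27 ± 0.25) and Lyz1 (5.57 ± 0.22), whose value is uncertain because of its near-identical copy Lyz2. Of the border macrophage markers 11 of 15 rose, 0 fell and 4 did not pass (12 up and 1 down adjusted over the list alone; camera adjusted p = 2.77e-08; adjusted p = 0.00585 with an estimated correlation). Among them were Ms4a7 (8.11 ± 0.26) and Pf4 (8.67 ± 0.68). Of the neutrophil markers 13 of 15 rose, 0 fell and 2 did not pass (14 up and 0 down adjusted over the list alone; camera adjusted p = 1.21e-09; adjusted p = 0.0696 with an estimated correlation). Among them were S100a9 (8.68 ± 0.49) and Il1r2 (6.76 ± 0.43). The median level of the 16 monocyte markers was 0.346 FPKM in Sham and 137 FPKM in MCAO, and 9 of them were below 1 FPKM in Sham. The dendritic cell markers went both ways: 5 of 11 rose, 2 fell and 4 did not pass (5 up and 2 down adjusted over the list alone; camera adjusted p = 0.477). Class II genes led the antigen presentation list, in which 10 of 19 rose, 2 fell and 7 did not pass (11 up and 2 down adjusted over the list alone; camera adjusted p = 0.00268; adjusted p = 0.211 with an estimated correlation). H2-Aa rose from 1.91 ± 1.22 to 1852 ± 837 FPKM and Cd74, the invariant chain gene, from 20.8 ± 12.1 to 1302 ± 686 FPKM.

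**Figure D2:**
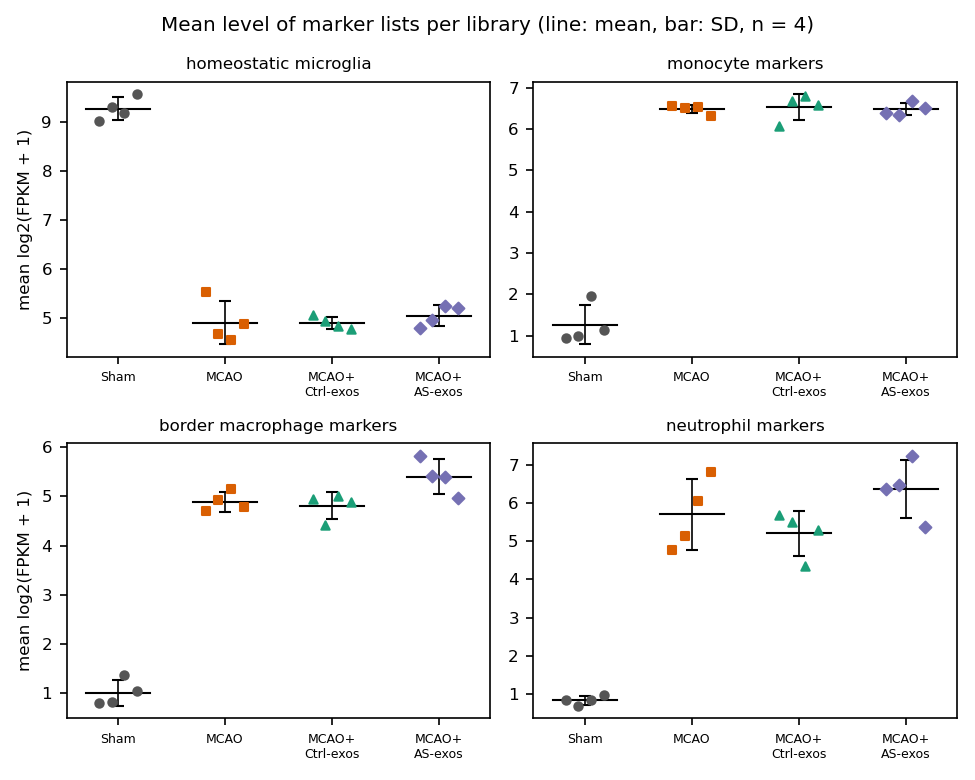
Mean log2(FPKM + 1) over the tested members of 4 marker lists, 1 point per library, with the group mean as a line and the SD as a bar (n = 4). Homeostatic microglia genes are lower and the other 3 lists higher in each MCAO group than in Sham.

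Of the glycolysis genes 15 of 17 rose, 1 fell and 1 did not pass (15 up and 1 down adjusted over the list alone; camera adjusted p = 6.71e-06; adjusted p = 0.0849 with an estimated correlation). Among them were Pkm (4.44 ± 0.31) and Pgam1 (2.78 ± 0.21). Of the oxidative phosphorylation genes 26 of 41 rose, 0 fell and 15 did not pass (26 up and 0 down adjusted over the list alone; camera adjusted p = 1.35e-05; adjusted p = 0.349 with an estimated correlation). Of the cytosolic ribosome genes 23 of 40 rose, 1 fell and 16 did not pass (26 up and 1 down adjusted over the list alone; camera adjusted p = 1.11e-04; adjusted p = 0.432 with an estimated correlation). Of the proliferation genes 20 of 25 rose, 0 fell and 5 did not pass (22 up and 0 down adjusted over the list alone; camera adjusted p = 1.59e-04; adjusted p = 0.314 with an estimated correlation). Among them was Mcm6 (3.36 ± 0.42). NRF2 targets, genes of the oxidant response, rose in 13 of 17 cases and none fell (13 up and 0 down adjusted over the list alone; camera adjusted p = 5.89e-06; adjusted p = 0.0282 with an estimated correlation). Among them were Srxn1 (4.61 ± 0.34) and Gsr (4.25 ± 0.34). Of the apoptosis and p53 target genes 9 of 18 rose, 2 fell and 7 did not pass (10 up and 2 down adjusted over the list alone; camera adjusted p = 0.0186; adjusted p = 0.131 with an estimated correlation). Among them were Bax (2.92 ± 0.27) and Cdkn1a (2.94 ± 0.34). Immediate early genes fell: 2 of 22 rose, 14 fell and 6 did not pass (2 up and 15 down adjusted over the list alone; camera adjusted p = 1.07e-07; adjusted p = 0.0263 with an estimated correlation), and Egr1 (-4.14 ± 0.22) and Fos (-2.01 ± 0.21) fell while Nr4a1 (4.66 ± 0.47) rose.

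Ferroptosis is iron-dependent cell death by lipid peroxidation, which the series title names. As for the other lists of MCAO against Sham, levels are of all sorted cells, whose monocyte, border macrophage and neutrophil markers were higher too. A change within microglia thus cannot be told apart here from a change in which cells were sorted. Of the genes that protect from it 14 of 24 rose, 1 fell and 9 did not pass (15 up and 1 down adjusted over the list alone; camera adjusted p = 0.00320; adjusted p = 0.0647 with an estimated correlation). Gpx4, whose product reduces lipid peroxides, rose from 337 ± 78.3 to 698 ± 106 FPKM. The ferritin heavy chain gene Fth1 rose from 3862 ± 515 to 14742 ± 1846 FPKM and the cystine importer gene Slc7a11 from 0.200 ± 0.230 to 5.14 ± 3.34 FPKM. The genes that promote ferroptosis went both ways, and 8 of 21 rose, 4 fell and 9 did not pass (8 up and 4 down adjusted over the list alone; camera adjusted p = 0.379). Cybb, the NADPH oxidase gene, rose (5.69 ± 0.27), while Acsl4, whose product activates polyunsaturated fatty acids, fell from 31.4 ± 11.1 to 13.7 ± 2.55 FPKM. The median of this list was 0.08, and -0.08 with quantile normalization and 0.42 with the length and GC trends removed. Its mean was 0.88, and fry, unlike camera, called it up (adjusted p = 6.86e-08). Fry called 23 of the 26 lists of this comparison, 21 up and 2 down. Of the iron handling genes 14 of 24 rose, 5 fell and 5 did not pass (16 up and 5 down adjusted over the list alone; camera adjusted p = 0.0564). Hmox1, which encodes the heme-degrading oxygenase, rose from 18.3 ± 14.8 to 839 ± 368 FPKM and the iron exporter gene Slc40a1 fell from 80.3 ± 42.0 to 4.01 ± 4.2 FPKM. Of the pro-inflammatory mediators 9 of 27 rose, 12 fell and 6 did not pass (9 up and 12 down adjusted over the list alone). Their median was -0.50, their mean 0.09 and the direction of camera down (adjusted p = 0.295). Il1b rose from 4.74 ± 7.13 to 544 ± 239.9 FPKM and Ccl2 rose from 164 ± 50.5 to 1018 ± 229 FPKM. Il6 fell from 26.5 ± 13.8 to 0.0150 ± 0.0300 FPKM, Cd86 fell from 198 ± 37.5 to 23.5 ± 12.6 FPKM and Cxcl10 fell from 94.1 ± 107 to 8.84 ± 11 FPKM. Tnf did not pass (-0.50 ± 0.45, adjusted p = 0.394).

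Among the other lists, of the lysosome and phagocytosis genes 13 of 32 rose, 6 fell and 13 did not pass (14 up and 6 down adjusted over the list alone; camera adjusted p = 0.477). The cathepsin gene Ctsb rose (2.93 ± 0.17). Of the complement genes 8 of 13 rose, 4 fell and 1 did not pass (8 up and 4 down adjusted over the list alone; camera adjusted p = 0.228). Cfp rose (7.26 ± 0.26) and C1qb fell (-1.65 ± 0.23). Of the hypoxia genes 7 of 16 rose, 5 fell and 4 did not pass (7 up and 5 down adjusted over the list alone; camera adjusted p = 0.379). Vegfa rose (4.33 ± 0.55). Of the interferon response genes 11 of 28 rose, 3 fell and 14 did not pass (12 up and 3 down adjusted over the list alone; camera adjusted p = 0.228). Ifitm3 rose (3.88 ± 0.51). Of the cholesterol synthesis genes 3 of 19 rose, 0 fell and 16 did not pass (3 up and 0 down adjusted over the list alone; camera adjusted p = 0.484). Of the unfolded protein response genes 4 of 18 rose, 8 fell and 6 did not pass (5 up and 8 down adjusted over the list alone). Their median was 0.28 and the direction of camera down (adjusted p = 0.421). In all, 16 of 26 lists moved (14 up and 2 down), and 8 of them held with an estimated correlation. Sham replicates 1 to 3 were low in GC-rich genes, with a median of -1.16, -0.59 and -0.72 log2 against the MCAO mean over the 20% of genes with the highest GC content, against -0.21 in replicate 4.

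The comparison of MCAO+Ctrl-exos with MCAO asks what exosome injection as such changed after MCAO. Few single genes differed. The oxidative phosphorylation and ribosome lists were shifted upward by camera with its preset correlation, but not with an estimated one (adjusted p = 0.288 for both). Only 1 of 41 and 0 of 40 of their members passed, and both shifts were smaller with the trends in transcript length and GC content removed. Uqcr11, a subunit gene of respiratory complex III, rose from 559 ± 47.8 to 1464 ± 362 FPKM (n = 4 per group; log2 fold change 1.36 ± 0.20, adjusted p = 0.00625). The other genes that rose were Ccdc58 (1.93 ± 0.34), the mitochondrial ribosome gene Mrps16 (1.55 ± 0.28), the immunophilin gene Fkbp2 (1.43 ± 0.27) and the prefoldin gene Pfdn5 (1.41 ± 0.24). The 3 genes that fell were chosen for naming after their values were seen. Rpgrip1 fell from 25.9 ± 10.1 to 0.285 ± 0.268 FPKM, Gstp2 from 17.6 ± 6.91 to 0.113 ± 0.135 FPKM and Zfp930 from 7.45 ± 3.25 to 0.825 ± 0.983 FPKM. Gstp2 has close copies, so its value is uncertain. These 8 genes were all that passed among 10846, against 1181 at an unadjusted p below 0.05. Values did not overlap for 649 genes (5.98%), where chance gives 2.86% on average, with a spread that was not computed. The median of all genes was -0.14, which quantile normalization brought to -0.03. With totals scaled to be equal, 2 genes were called higher and 3 lower.

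The median log2 fold change was 0.53 over 40 cytosolic ribosome genes (camera adjusted p = 1.11e-20; adjusted p = 0.288 with an estimated correlation) and 0.52 over 41 oxidative phosphorylation genes (camera adjusted p = 6.29e-20; adjusted p = 0.288 with an estimated correlation). Of the ribosome genes 0 of 40 rose, 0 fell and 40 did not pass (14 up and 0 down adjusted over the list alone). Of the oxidative phosphorylation genes 1 of 41 rose, 0 fell and 40 did not pass (12 up and 0 down adjusted over the list alone). Rpl18 was at 1114 ± 305 FPKM in MCAO and 2428 ± 649 in MCAO+Ctrl-exos, and Rps19 at 2188 ± 786 and 4614 ± 1354, neither past the threshold (adjusted p = 0.0655 and 0.112). Transcripts of these lists are short, with median lengths of 774 and 612 bases against 2147 over all genes. In MCAO+Ctrl-exos replicates 2 to 4 the shortest 20% of transcripts lay 0.19 to 0.21 log2 above the MCAO mean, in replicate 1 at 0.00. With the trends in length and GC content removed, the medians were 0.17 and 0.14.

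Smaller upward shifts passed camera for disease-associated microglia genes (median 0.12, camera adjusted p = 0.0437; adjusted p = 0.542 with an estimated correlation), lipid export and storage (0.12; adjusted p = 0.288 with an estimated correlation), lysosome and phagocytosis (0.12; adjusted p = 0.542 with an estimated correlation) and the unfolded protein response (0.10; adjusted p = 0.542 with an estimated correlation). These 4 medians were -0.09, -0.09, -0.08 and -0.11 with totals scaled to be equal, which moved the median of all genes to -0.32. Immediate early genes were shifted down (median -0.29, camera adjusted p = 0.0437; adjusted p = 0.542 with an estimated correlation), with Egr1 at 75.9 ± 16.9 FPKM in MCAO and 37.4 ± 6.42 in MCAO+Ctrl-exos (adjusted p = 0.112). No member of these 5 lists passed over all genes; adjusted over each list alone, 2 lipid genes, 1 lysosome gene and 2 genes of the unfolded protein response rose and 2 immediate early genes fell. None of the 366 members of the other 19 lists, counted list by list, passed limma, and their camera adjusted p ranged from 0.237 to 0.934. At an unadjusted p below 0.05 the ferroptosis-promoting list held 0 genes and the ferroptosis-protecting list 4. Gpx4 stood at 1146 ± 328 FPKM (log2 fold change 0.69 ± 0.22, adjusted p = 0.260), Slc7a11 at 3.37 ± 0.817, P2ry12 at 28.6 ± 13.3 and Tmem119 at 40.7 ± 16.7.

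The gene count depended on single libraries: 89 genes passed without MCAO+Ctrl-exos replicate 1, 5 without replicate 2, 5 without replicate 3, 2 without replicate 4, 4 without MCAO replicate 1 and 5 without MCAO replicate 3. Rpgrip1 and Gstp2 were among the genes in each of those fits that called 5 genes or fewer, with Uqcr11 in all of them but the fit without MCAO+Ctrl-exos replicate 4. The others, named after their values were seen, included Ccdc58 without MCAO replicate 1, Fdx2 without MCAO replicate 3, Zfp930 and H4c2 without MCAO+Ctrl-exos replicate 2, and Lat and Mfsd7a without MCAO+Ctrl-exos replicate 3. Camera called the ribosome and oxidative phosphorylation lists whichever library was left out. The disease-associated call ended without MCAO replicate 2 or 4 or MCAO+Ctrl-exos replicate 3 (adjusted p up to 0.178). The lipid call ended without MCAO replicate 1 or 4 or MCAO+Ctrl-exos replicate 1, 2, 3 or 4 (adjusted p up to 0.139). The lysosome call ended without MCAO replicate 2 or 4 or MCAO+Ctrl-exos replicate 1 or 3 (adjusted p up to 0.178). The immediate early call ended without MCAO replicate 1, 3 or 4 or MCAO+Ctrl-exos replicate 2, 3 or 4 (adjusted p up to 0.145), and the call for the unfolded protein response without MCAO replicate 1 or 3 or MCAO+Ctrl-exos replicate 1, 2 or 3 (adjusted p up to 0.352).

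The comparison of MCAO+AS-exos with MCAO+Ctrl-exos asks whether AS-exos, the exosomes of the series title, changed the cells beyond what Ctrl-exos did. Single genes differed, among them Lcn2, Ctsc, Cd33 and Siglece, which were higher with AS-exos, and Uqcr11, Ndufa1 and Hspa5, which were lower. At least as many genes passed in 5 of the 35 splits of these 8 libraries, the real one included, so chance is not excluded. Lcn2, which encodes the siderophore-binding lipocalin 2 of neutrophil granules, rose from 14.9 ± 15.2 to 170.4 ± 120.3 FPKM (n = 4 per group). In MCAO+AS-exos replicate 4 it was at 43.65 FPKM, against 35.28 in MCAO+Ctrl-exos replicate 4. Ctsc, the gene of cathepsin C, rose from 135 ± 24.9 to 449 ± 151 FPKM. The inhibitory receptor genes Cd33 and Siglece rose from 11.4 ± 5.22 to 65.1 ± 29.7 FPKM and from 3.65 ± 0.890 to 18.7 ± 8.29 FPKM. Uqcr11 and Ndufa1, subunit genes of respiratory complexes III and I, fell from 1464 ± 362 to 654 ± 133 FPKM and from 1592 ± 342 to 781 ± 231 FPKM. Hspa5, which encodes the chaperone BiP, fell from 631 ± 104 to 323 ± 44.7 FPKM. In the MCAO libraries Uqcr11 was at 505 to 621, Ndufa1 at 798 to 1210 and Hspa5 at 342 to 492 FPKM, below the Ctrl-exos means. These falls thus start from a Ctrl-exos level above that of MCAO. In limma 31 of 10846 genes passed, 17 higher and 14 lower, against 2127 at an unadjusted p below 0.05. Quantile normalization called 88 genes (43 higher and 45 lower), and removal of the trends in transcript length and GC content 55 (16 higher and 39 lower). Values did not overlap for 1107 genes (10.2%), where chance gives 2.86% on average, with a spread that was not computed.

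The named rises in log2 fold change (± SE) were Lcn2 (3.90 ± 0.77), Cd33 (2.40 ± 0.38), Cirbp (2.37 ± 0.43), Trmt10c (2.10 ± 0.36), Siglece (2.02 ± 0.35), Tmem159 (1.89 ± 0.34), P2ry13 (1.81 ± 0.38), Tmem181a (1.77 ± 0.33), Ctsc (1.66 ± 0.28) and Cr1l (1.45 ± 0.30), with adjusted p from 0.0221 to 0.0451. Cirbp encodes a cold-inducible RNA-binding protein and P2ry13 a purinergic receptor of microglia. The named falls were Ube2s (-2.30 ± 0.38), Hras (-2.25 ± 0.47), Ptov1 (-1.90 ± 0.36), Maf (-1.69 ± 0.34), Nipbl (-1.66 ± 0.34), Supt16 (-1.59 ± 0.32), Uqcr11 (-1.15 ± 0.20), Trappc4 (-1.12 ± 0.22), Ndufa1 (-1.04 ± 0.22) and Hspa5 (-0.96 ± 0.19), with adjusted p from 0.0223 to 0.0441. Ube2s encodes a ubiquitin-conjugating enzyme, Hras a small GTPase, Maf a transcription factor of macrophages, Nipbl the cohesin loader and Supt16 a histone chaperone. The count was 3, 1 and 1 without MCAO+AS-exos replicate 1, 2 or 3, 1297 without replicate 4, and 80, 3, 15 and 9 without MCAO+Ctrl-exos replicate 1, 2, 3 or 4. Rpgrip1 (3.49 ± 0.36), named after its values were seen, was the gene that passed without MCAO+AS-exos replicate 2 and without replicate 3. Cd33 and Rpgrip1 passed with Mgp without MCAO+AS-exos replicate 1 and with Cirbp without MCAO+Ctrl-exos replicate 2. The 31 genes were all called without MCAO+AS-exos replicate 4.

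**Figure D3:**
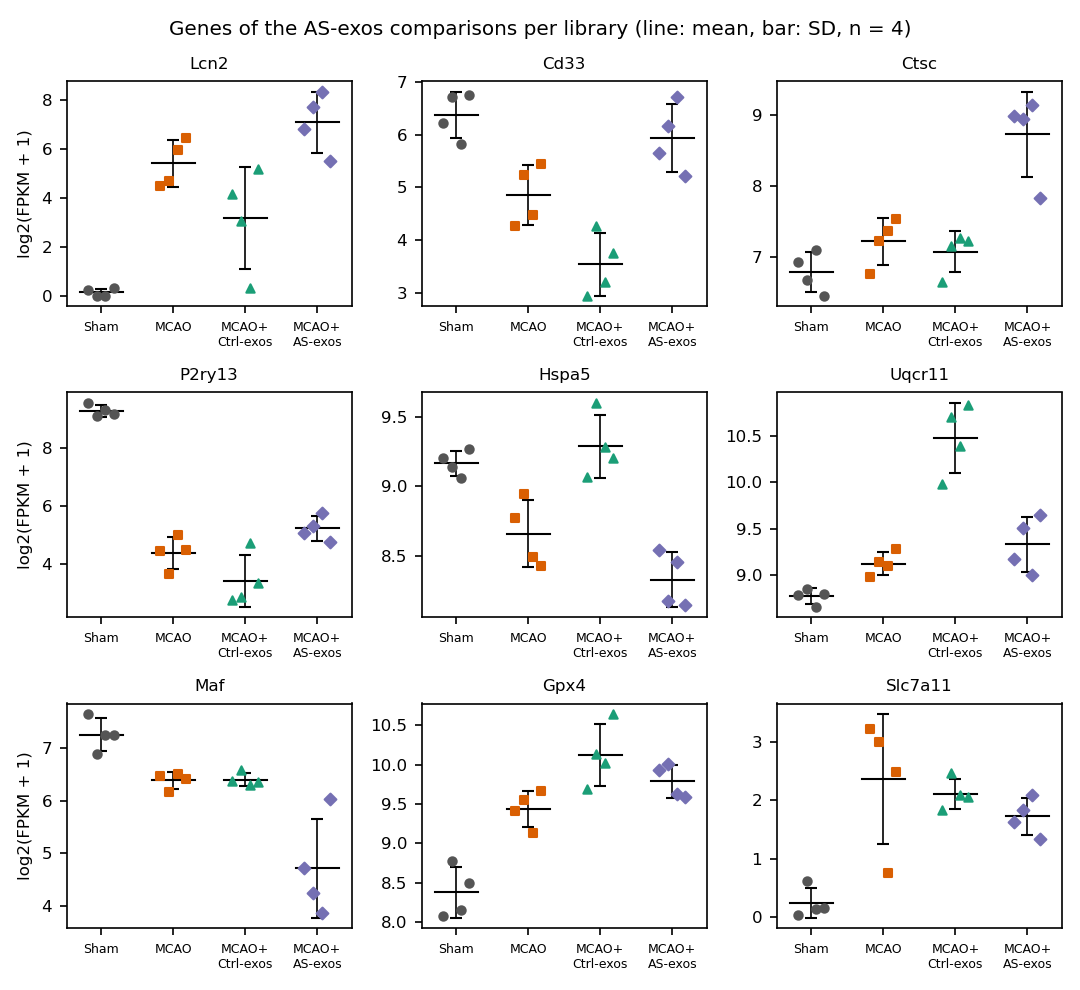
log2(FPKM + 1) of 9 genes in the 16 libraries, with the group mean as a line and the SD as a bar (n = 4). With AS-exos, Lcn2, Cd33, Ctsc and P2ry13 are higher and Hspa5, Uqcr11 and Maf lower than with Ctrl-exos, while Gpx4 and Slc7a11 did not pass the test.

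No ferroptosis gene passed between AS-exos and Ctrl-exos. Of 21 promoting genes none passed limma over all genes or adjusted over the list alone, and 5 were higher and 3 lower at an unadjusted p below 0.05 (median 0.22, camera adjusted p = 0.142). The median was -0.04 with the length and GC trends removed. Of 24 protecting genes none passed either, over all genes or adjusted over the list alone, and 1 was higher and 3 lower at an unadjusted p below 0.05 (median -0.09, camera adjusted p = 0.938). Gpx4 was at 1146 ± 328 FPKM with Ctrl-exos and 889 ± 130.4 with AS-exos (log2 fold change -0.34 ± 0.22, adjusted p = 0.414). Slc7a11 was at 3.37 ± 0.817 and 2.37 ± 0.731 and Acsl4 at 11.7 ± 5.01 and 8.82 ± 1.95. Fth1 was at 18291 ± 2891 and 19572 ± 3266 and the ferritin receptor gene Ncoa4 at 18.2 ± 3.86 and 32.3 ± 5.69 (adjusted p = 0.113). Without MCAO+AS-exos replicate 4, an omission chosen for mention after its values were seen, 3 promoting genes (Atg5, Hmgb1 and Vdac3) were called higher and 2 (Slc39a14 and Keap1) lower, and 2 protecting genes (Pcbp1 and Pcbp2) lower. Of 24 iron handling genes Lcn2 was the only one to pass, over all genes and over the list alone (camera adjusted p = 0.237). Hmox1 was at 607 ± 455 and 1451 ± 559 FPKM (adjusted p = 0.189).

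Mediators of inflammation did not pass either: of 27 genes none passed over all genes and 1, Ccl3 (1.07 ± 0.27), rose adjusted over the list alone (camera adjusted p = 0.347). There were 1 higher and 2 lower at an unadjusted p below 0.05. Il1b was at 521 ± 132 FPKM with Ctrl-exos and 1039.7 ± 410.2 with AS-exos (adjusted p = 0.326). Tnf was at 24.6 ± 8.94 and 38.2 ± 22.7 (adjusted p = 0.563), and Ccl2 at 796 ± 231 and 1044 ± 147 (adjusted p = 0.347). Arg1 was at 725 ± 225 and 2182 ± 971 (adjusted p = 0.0502). Of the alternative activation genes 0 of 16 rose, 0 fell and 16 did not pass (4 up and 2 down adjusted over the list alone; camera adjusted p = 0.524). Of the homeostatic microglia genes 1 of 25 rose, 0 fell and 24 did not pass (2 up and 2 down adjusted over the list alone), P2ry13 being the one that rose (camera adjusted p = 0.237).

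Neutrophil markers were shifted up (median 1.12, camera adjusted p = 3.17e-05; adjusted p = 0.348 with an estimated correlation): 1 of 15 rose, 0 fell and 14 did not pass (6 up and 0 down adjusted over the list alone). S100a8 was at 1683 ± 502 and 4269 ± 1237 FPKM (adjusted p = 0.104). The mean log2 level of the neutrophil markers was 6.35, 6.48 and 7.24 in MCAO+AS-exos replicates 1 to 3, while replicate 4, at 5.38, lay within the MCAO+Ctrl-exos range of 4.36 to 5.70. Replicate 4 lay within the MCAO+Ctrl-exos range for the border macrophage markers too (4.96, range 4.42 to 5.02). The neutrophil level of the MCAO libraries, without exosomes, ranged from 4.77 to 6.81. Lysosome and phagocytosis genes were shifted up (median 0.41, camera adjusted p = 0.00119; adjusted p = 0.348 with an estimated correlation): 1 of 32 rose, 0 fell and 31 did not pass (6 up and 2 down adjusted over the list alone). So were border macrophage markers (median 0.42, camera adjusted p = 0.00871; adjusted p = 0.348 with an estimated correlation). Antigen presentation genes were shifted up as well (median 0.40, camera adjusted p = 0.0257; adjusted p = 0.413 with an estimated correlation) and complement genes (0.29, camera adjusted p = 0.0437; adjusted p = 0.348 with an estimated correlation). No member of these 3 lists passed over all genes. Of them 1 border macrophage gene, 0 antigen presentation genes and 4 complement genes rose adjusted over each list alone, and 1 complement gene fell. With the length and GC trends removed the medians of the neutrophil, lysosome, border macrophage, antigen presentation and complement lists were 1.09, 0.19, 0.55, 0.16 and 0.27. Cd68 was at 1234 ± 157 and 2476 ± 694 FPKM (adjusted p = 0.0672). Cd74 was at 1435 ± 615 and 3118 ± 732 (adjusted p = 0.115) and C5ar1 at 116 ± 25.9 and 365 ± 149 (adjusted p = 0.0659).

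Oxidative phosphorylation genes were shifted down (median -0.60, camera adjusted p = 8.44e-10; adjusted p = 0.348 with an estimated correlation): 0 of 41 rose, 2 fell and 39 did not pass (1 up and 15 down adjusted over the list alone). Cytosolic ribosome genes were too (median -0.66, camera adjusted p = 8.44e-10; adjusted p = 0.364 with an estimated correlation): 0 of 40 rose, 0 fell and 40 did not pass (1 up and 25 down adjusted over the list alone). Rplp1 was at 5785 ± 1549.7 and 2741 ± 965 FPKM (adjusted p = 0.0572). With the length and GC trends removed these medians were -0.54 and -0.64. Against MCAO the AS-exos medians were -0.04 and -0.09, and -0.39 and -0.36 with those trends removed. Without MCAO+AS-exos replicate 4, an omission chosen for mention after its values were seen, 14 oxidative phosphorylation genes fell and 0 rose against Ctrl-exos. Of the ribosome genes 23 fell and 1 rose in that fit. Hspa5 was the member of the unfolded protein response list that fell, with 3 of 18 lower adjusted over the list alone (camera adjusted p = 0.238). The hypoxia list moved down by fry (adjusted p = 0.0430) and not by camera (adjusted p = 0.142; median -0.63). The 19 lists that camera did not call had adjusted p from 0.0928 to 0.993. With an estimated correlation camera called none of the 26 lists, 2 of them having an unadjusted p below 0.05. The antigen presentation call of the preset correlation ended without MCAO+Ctrl-exos replicate 1 or 4 or MCAO+AS-exos replicate 4 (adjusted p up to 0.132) and the border macrophage call without MCAO+Ctrl-exos replicate 2 or MCAO+AS-exos replicate 1 (adjusted p up to 0.0614). The complement call ended without MCAO+Ctrl-exos replicate 1, 2 or 4 or MCAO+AS-exos replicate 1 or 4 (adjusted p up to 0.105).

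The comparison of MCAO+AS-exos with MCAO asks what AS-exos changed against occlusion without exosomes. More genes fell than rose, with Ctsc, Fcgr4, Cd68 and C1qb among those that rose and Cebpb, Jun and Srrm2 among those that fell. Ctsc rose from 151 ± 32.8 to 449 ± 151 FPKM and the Fc receptor gene Fcgr4 from 121 ± 31.8 to 321 ± 80.4 FPKM (n = 4 per group). The scavenger receptor gene Cd68 rose from 1271 ± 232 to 2476 ± 694 FPKM and the complement gene C1qb from 2865 ± 646 to 5383 ± 1442 FPKM. Cebpb, a transcription factor gene of myeloid cells, fell from 219 ± 58.5 to 46.7 ± 73.6 FPKM. Jun fell from 98.3 ± 28.8 to 25.4 ± 24.2 FPKM and the splicing factor gene Srrm2 from 126 ± 7.87 to 33.0 ± 32.9 FPKM. In limma 666 genes passed, 115 higher and 551 lower, so 82.7% were lower; 2785 had an unadjusted p below 0.05. The median of all genes was -0.17; quantile normalization brought it to -0.02, with 318 genes called and 69.8% of them lower. With totals scaled to be equal it was -0.27, with 92.1% lower. Values did not overlap for 1561 genes (14.4%), where chance gives 2.86% on average, with a spread that was not computed.

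The named rises were Serhl (3.08 ± 0.66), H2aw (2.81 ± 0.61), Timm21 (2.12 ± 0.49), Tmem176b (1.98 ± 0.40), Tmem159 (1.91 ± 0.34), Commd9 (1.82 ± 0.39), Ift27 (1.78 ± 0.42), Ccdc58 (1.72 ± 0.34), Cirbp (1.68 ± 0.43) and Clp1 (1.64 ± 0.42), with adjusted p from 0.0153 to 0.0349. Timm21 encodes a subunit of the mitochondrial import machinery and Ift27 a protein of intraflagellar transport. Among the named falls were Cebpb (-3.40 ± 0.69), Ptms (-2.32 ± 0.54), Srrm2 (-2.30 ± 0.41), Jun (-2.22 ± 0.41), Slc10a7 (-2.14 ± 0.35), Alyref (-2.13 ± 0.40), Mafg (-2.12 ± 0.41), Btg3 (-2.09 ± 0.46) and Rbbp6 (-2.03 ± 0.32), with adjusted p from 0.0124 to 0.0273. Alyref encodes an mRNA export factor and Mafg a partner of NRF2. Cebpb stood at 10.7, 14.2 and 5.03 FPKM in MCAO+AS-exos replicates 1 to 3 and at 157 in replicate 4, and Jun at 16, 12.3 and 11.8 and at 61.6. The genes that fell had longer transcripts, with a median of 2876 bases against 1272 for those that rose and 2147 for all genes. The longest 20% of transcripts lay at -0.78 to -0.71 log2 against the MCAO mean in replicates 1 to 3 and at -0.16 in replicate 4. The 1 in 20 genes with the highest GC content lay at -0.55, -0.39 and -0.61 in replicates 1 to 3 and at 0.02 in replicate 4. For the 20% with the highest GC content the values were -0.40, -0.21, -0.30 and 0.01. For the 20% with the lowest they were -0.19, -0.31, -0.16 and -0.13. With the trends in length and GC content removed, 377 genes passed, 298 of them shared with the 666.

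Of the lysosome and phagocytosis genes 5 of 32 rose, 0 fell and 27 did not pass (12 up and 2 down adjusted over the list alone; median 0.41, camera adjusted p = 1.43e-06; adjusted p = 0.152 with an estimated correlation). Among them were Ctss (0.62 ± 0.17) beside Ctsc, Fcgr4 and Cd68. Of the complement genes 2 of 13 rose, 1 fell and 10 did not pass (2 up and 1 down adjusted over the list alone; median 0.36, camera adjusted p = 0.0431; adjusted p = 0.152 with an estimated correlation). C1qa (1.12 ± 0.31) and C1qb rose, and Itgam, which encodes the CD11b chain that was stained, fell (-1.0 ± 0.29). Disease-associated microglia genes (median 0.31, camera adjusted p = 4.55e-04; adjusted p = 0.152 with an estimated correlation) and lipid export and storage genes (0.18, camera adjusted p = 0.0229; adjusted p = 0.152 with an estimated correlation) were shifted up. So were border macrophage markers (median 0.57, camera adjusted p = 0.00621; adjusted p = 0.152 with an estimated correlation), neutrophil markers (0.55, camera adjusted p = 0.00324; adjusted p = 0.480 with an estimated correlation) and antigen presentation genes (0.44, camera adjusted p = 0.0336; adjusted p = 0.480 with an estimated correlation). Their members that rose over all genes were Cd68, the phospholipid transfer gene Pltp (1.03 ± 0.28), Cd38 (0.91 ± 0.27) and the class II gene H2-DMa (1.0 ± 0.26), while H2-Q4, uncertain because of its near-identical copies, fell (-1.69 ± 0.42). No neutrophil marker passed. Adjusted over each list alone, 1 disease-associated, 1 lipid, 1 border macrophage, 0 neutrophil and 2 antigen presentation genes rose, and 1 of the last fell. With the length and GC trends removed the medians of the disease-associated and antigen presentation lists were -0.01 and -0.06. The median of the lipid list was 0.05 with totals scaled to be equal, 0.15 with quantile normalization and 0.19 with the trends removed. The ribosome and oxidative phosphorylation lists had medians of -0.09 and -0.04 (camera adjusted p = 0.494 and 0.531). These were -0.36 and -0.39 with the trends removed, and -0.23 and -0.13 with quantile normalization.

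Among immediate early genes 0 of 22 rose, 4 fell and 18 did not pass (0 up and 6 down adjusted over the list alone). Jun, Ier5 (-1.71 ± 0.40), Klf2 (-1.48 ± 0.40) and Jund (-2.22 ± 0.63) fell (camera adjusted p = 0.268). Among hypoxia genes 0 of 16 rose, 4 fell and 12 did not pass (0 up and 4 down adjusted over the list alone). Ddit4 (-1.61 ± 0.41), Mxi1 (-1.32 ± 0.34), Vegfa (-1.91 ± 0.55) and the oxygen sensor gene Egln1 (-1.17 ± 0.34) fell (camera adjusted p = 0.733), while the median of the list was -0.10 and 0.03 with quantile normalization. Of the ferroptosis-promoting genes 1 of 21 rose, 2 fell and 18 did not pass (1 up and 2 down adjusted over the list alone; camera adjusted p = 0.190). Vdac3 rose (1.03 ± 0.25), and Slc39a14 (-1.50 ± 0.40) and Keap1 (-1.51 ± 0.43) fell. Of the protecting genes 1 of 24 rose, 2 fell and 21 did not pass (1 up and 3 down adjusted over the list alone; camera adjusted p = 0.962). The ferritin light chain gene Ftl1 rose from 13567 ± 1036 to 26278 ± 9264 FPKM, and Pcbp1 (-1.07 ± 0.29) and the glutathione synthesis gene Gclc (-1.34 ± 0.38) fell. Of the iron handling genes 1 of 24 rose, 3 fell and 20 did not pass (2 up and 5 down adjusted over the list alone; camera adjusted p = 0.556). Gpx4 was at 698 ± 106 FPKM in MCAO and 889 ± 130.4 with AS-exos (adjusted p = 0.328) and Slc7a11 at 5.14 ± 3.34 and 2.37 ± 0.731 (adjusted p = 0.387). Il1b was at 544 ± 239.9 and 1039.7 ± 410.2 (adjusted p = 0.268) and Apoe at 11862 ± 1872 and 20575 ± 5603 (adjusted p = 0.0746). None of 27 pro-inflammatory mediators passed in limma (camera adjusted p = 0.227), with 0 higher and 1 lower at an unadjusted p below 0.05. The 19 lists not called by camera had adjusted p from 0.126 to 0.962.

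The count rested on single libraries. Without MCAO+AS-exos replicate 1, 2 or 3 it was 2 (Ly6c1 and Mgp, named after their values were seen), 0 and 0 in limma, with 1918 and 1933 genes at an unadjusted p below 0.05 where it was 0. Without replicate 4 it was 2024, and without MCAO replicate 1, 2, 3 or 4 it was 37, 133, 109 and 75. The antigen presentation call ended without MCAO replicate 3 or 4 or MCAO+AS-exos replicate 4 (adjusted p up to 0.0955) and the complement call without MCAO replicate 2 or 4 or MCAO+AS-exos replicate 4 (adjusted p up to 0.109).

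**Figure D4:**
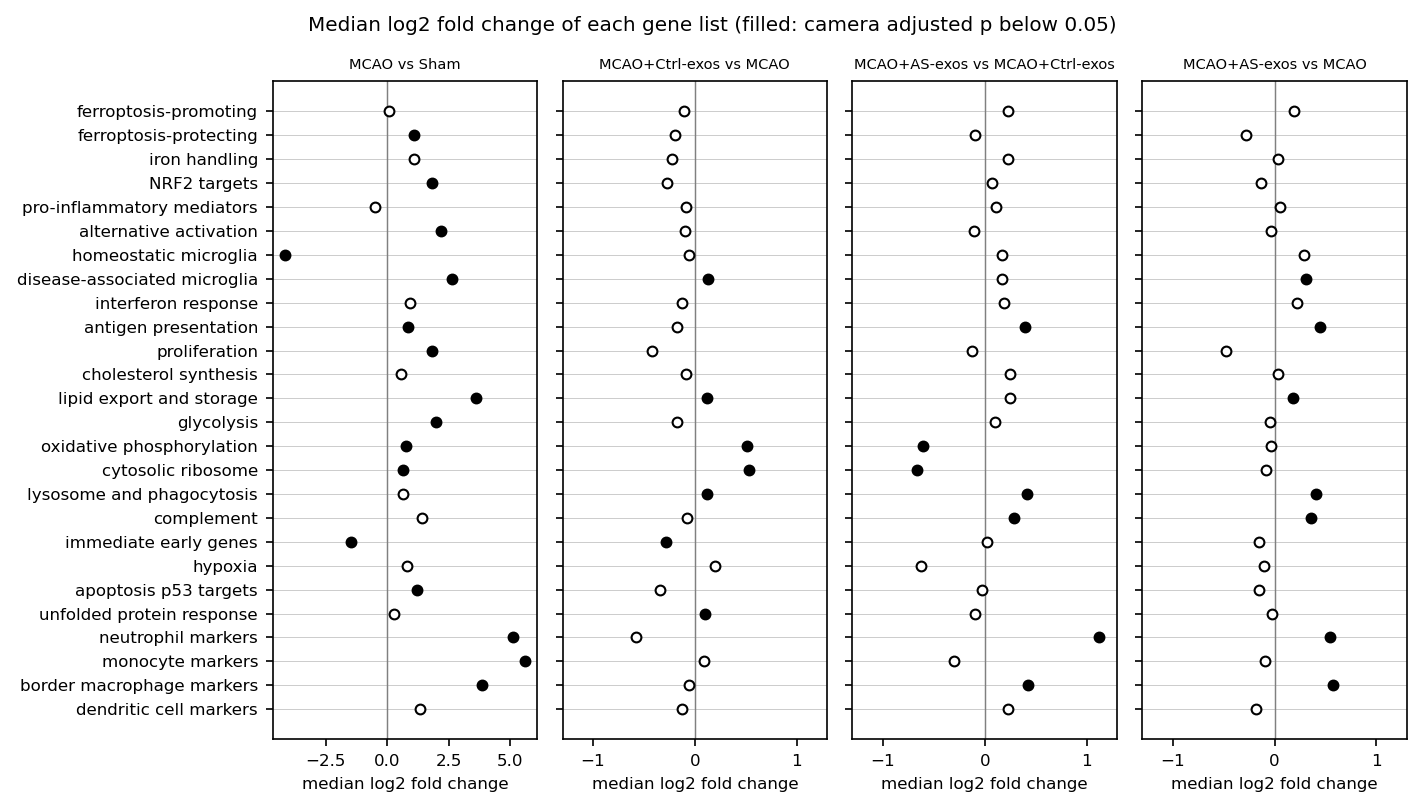
Median log2 fold change of each of 26 gene lists in the 4 comparisons, filled where the camera adjusted p with a preset correlation is below 0.05; the axis of the first panel is wider than those of the others. The ribosome and oxidative phosphorylation lists lie at 0.53 and 0.52 with Ctrl-exos against MCAO and at -0.66 and -0.60 with AS-exos against Ctrl-exos.

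Whether the AS-exos difference ran along the injury difference was asked across genes. The log2 fold changes of MCAO+AS-exos against MCAO+Ctrl-exos and of MCAO against Sham, which share no library, correlated at r = -0.103 (Spearman's rho = -0.137); genes are not independent replicates, and 8 of the 35 splits of the 8 exosome libraries gave a value as far from 0. The fold changes of both exosome groups against the shared MCAO libraries correlated at r = 0.492. In simulations of unchanged groups, with the shared MCAO group drawn anew as well, the correlation was 0.572 ± 0.00668 (SD of 20 simulations). Genes were drawn independently there, so this SD leaves out the correlation between genes. It cannot be used to judge the differences from the observed values. The covariance was 0.197 against 0.118 simulated, a difference of 0.0790. With the MCAO libraries split between the comparisons, the mean r was 0.155 and the mean covariance 0.0805 over 6 splits. Ccdc58 and Mrps16 were called higher in both comparisons and Gstp2 lower in both, against 0.0530 and 0.152 genes for independent lists, and 0.10 on average in the simulations. Neither reference can show an excess, because the first ignores the shared MCAO libraries and the simulated groups hold no changed genes.

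Lists of lymphocyte, neural, vascular and erythroid markers had fewer than 5 tested members, and only their levels are given (single genes as mean ± SD, n = 4). The 9 neuron markers in the table had group medians of 0.0125 to 0.292 FPKM, and none was tested. The highest T and NK cell marker was Il7r, at 22.4 ± 9.82 FPKM in Sham and 13.2 ± 4.64 in MCAO+AS-exos, and the highest B cell marker was Cd79b in Sham at 32.3 ± 17.6 FPKM. Slc1a3, an astrocyte marker, was at 76.2 ± 22.6 FPKM in Sham, and Gja1 at 7.46 ± 3.69 in MCAO. Trf, of the oligodendrocyte list, was at 294 ± 131 FPKM in Sham and 210.2 ± 73.8 in MCAO+AS-exos. Of the endothelial and mural markers Pecam1 was highest in Sham at 4.64 ± 2.41 FPKM and Ly6c1 in MCAO+AS-exos at 19.6 ± 21.3. The highest erythroid marker, Hba-a1 in MCAO, uncertain because of its copy Hba-a2, was at 16.6 ± 33.2 FPKM, a mean that rests on 1 library with the other 3 at 0. Of the focus genes, Alox15 stayed below 1 FPKM in the 16 libraries and was not tested, and Nos2 was not analysed here.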

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

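A set of 3 tests of this part was chosen only after the result they measure was seen: the spread of the ratios of microglia genes, the swap of labels and the single wrong label. The combined removal of trends and shift was written down before its own value was known, but after those of its parts. The test of different totals was set in advance on scaled totals and quantile normalization together, and it is read by that rule.

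Microglia identity genes were lower, and monocyte, border macrophage and neutrophil genes higher, in MCAO than in Sham. A trend with GC content and transcript length in the Sham libraries is argued against as the cause: with both trends removed 24 of 24 homeostatic genes were still called lower and 38 of 39 marker genes still called higher. If fewer microglia among the sorted cells were the whole cause, microglia genes would fall by like amounts; the SD of their log2 ratios was 2.86 against a median standard error of 0.422, with folds from 2.44 for Bin1 to 3309 for Slc2a5. That explanation may still hold in part and stays open, because other sorted cells, if they carry CD45 and CD11b, can hold some of these transcripts. Of the monocyte list 1 gene and of the border macrophage list 3 are also in the alternative activation list, and 1 neutrophil marker is an iron handling gene. A change of state after occlusion, the biological explanation of the design, stays open and untested.

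MCAO+AS-exos replicate 4 had the lowest mean correlation within its group, 0.915 against 0.956 to 0.962 for replicates 1 to 3. Such means were 0.905 to 0.920 in MCAO, 0.914 to 0.929 in MCAO+Ctrl-exos and 0.881 to 0.902 in Sham. The value of replicate 4 was thus within the range of the other groups, and those of replicates 1 to 3 were above it. A trend with transcript length and GC content is argued against as the whole cause, since with both removed its mean correlation with replicates 1 to 3 was 0.921, below 0.978, the lowest among those. A swap with MCAO+Ctrl-exos replicate 1 is argued against: that library correlated with MCAO+AS-exos replicates 1 to 3 at 0.887, below its lowest correlation with its own group, 0.909. A single library of another MCAO group under this label could have this profile, as replicate 4 correlated with the MCAO+Ctrl-exos libraries at 0.928, and cannot be told apart from a library that differs by chance, because the MCAO groups correlate almost as closely with each other. Replicates 1 to 3, with r of 0.979 to 0.985, may also share a source or a preparation, which was not tested.

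More genes were lower than higher in MCAO+AS-exos against MCAO, 82.7% of those called; in the fit of only the 8 libraries compared 58.1% of 31 genes were lower, and without MCAO+AS-exos replicate 1 neither of 2 was. With both trends removed 87.5% were lower, which argues against a trend with transcript length and GC content alone; the removal keeps the mean of each library, so a shift of all genes stays in that value. Different totals stay undecided by the rule set in advance, which asked for 75% or more under both scalings. With totals scaled to be equal 92.1% were lower, and with quantile normalization, which evens whole distributions and not totals alone, 69.8%. The mean total was higher with AS-exos (864667) than in MCAO (790590). Scaling thus moves AS-exos values down on average, so the 92.1% cannot decide the question. The trend together with a shift of all genes may explain part and stays open, with 71.2% lower with both removed. An effect of AS-exos, the biological explanation of the design, stays open too, as an untested one.

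Among 147 named genes and the library measures, 362 groups of 4 were tested with Dixon's test, and in 54 of them 1 library lay far from the others. The level of the test, about 1 in 20, holds for independent normal values. Here FPKM were tested without logs, some groups were near 0, and genes are not independent. Many genes were also named for a difference between groups. The counts are therefore descriptive and cannot show an excess over chance. MCAO+AS-exos replicate 4 held 20 of the 52 gene values among these, besides its mean correlation with its group. The rank correlation with transcript length was 0.0192 in MCAO+Ctrl-exos replicate 1 and -0.222 to -0.201 in the others of its group. Values below are in FPKM, with the range of the other 3 libraries of the group. MCAO+AS-exos replicate 4 had the highest value of Alyref (33.0; others 4.78 to 9.30), Btg3 (13.4; others 3.76 to 5.27), Cebpb (157; others 5.03 to 14.2), Hras (9.94; others 6.95 to 7.08), Ier5 (83.5; others 13.7 to 17.9), Itgam (146; others 52.0 to 62.7), Jun (61.6; others 11.8 to 16), Jund (64.6; others 3.11 to 4.51), Keap1 (11.8; others 2.93 to 4.09), Klf2 (65.7; others 19.2 to 21.2), Mafg (52.3; others 12.1 to 16.4), Nipbl (14.9; others 5.03 to 5.21), Pcbp1 (195; others 64.7 to 80.4), Ptms (108; others 10.3 to 18.4), Rbbp6 (11.6; others 4.2 to 5.14), Slc39a14 (13.7; others 4.11 to 5.63), Srrm2 (82.2; others 14.9 to 19.7) and Trappc4 (186; others 105 to 118) and the lowest value of Atg5 (45.4; others 70.3 to 74.8) and Cd68 (1441; others 2754 to 2919). MCAO+Ctrl-exos replicate 1 had the lowest value of Trappc4 (227; others 291 to 295). MCAO+Ctrl-exos replicate 2 had the highest value of Mgp (2.92; others 0.10 to 0.580). MCAO replicate 1 had the highest value of Cirbp (36.2; others 20.5 to 21.7), Crybb1 (11; others 0 to 0.160), Ecscr (36.2; others 5.33 to 8.76), Mfsd7a (0.650; others 0.02 to 0.0900), Sparc (72.5; others 2.11 to 6.39) and Tnf (78.0; others 19.5 to 26.2). MCAO replicate 2 had the highest value of Il6 (0.0600; others 0), Lat (0.200; others 0), Ly6c1 (3.05; others 0.240 to 0.330) and Mrps16 (80.4; others 34.4 to 39.5) and the lowest value of Acsl4 (9.89; others 14.7 to 15.3). MCAO replicate 3 had the highest value of H4c2 (0.240; others 0), Mgp (3.24; others 0 to 0.240) and Rpgrip1 (41.0; others 19.8 to 22.8) and the lowest value of Pfdn5 (202; others 266 to 273). MCAO replicate 4 had the highest value of Msr1 (187; others 144 to 148), Rps19 (3353; others 1629 to 1893) and Serhl (11.3; others 0 to 1.60). Sham replicate 1 had the highest value of Vegfa (2.40; others 0 to 0.160) and Vim (4.31; others 0.540 to 1.18) and the lowest value of Il1r2 (0; others 0.150 to 0.180). Sham replicate 3 had the highest value of Ifitm3 (467; others 34.0 to 78.9) and Pf4 (52.9; others 1.17 to 3.16). Sham replicate 4 had the highest value of Apoc2 (4.98; others 1.20 to 1.27), Cx3cr1 (1354; others 845 to 893), Il1b (15.4; others 0.5 to 1.72), Lgals3 (3.22; others 0.840 to 1.18), Lilrb4a (2.73; others 0.310 to 0.590) and S100a4 (36.3; others 1.54 to 2.06) and the lowest value of Cd86 (142; others 212 to 223).

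Each count was compared with those of the 35 splits of its 8 libraries. For genes, chance is excluded in MCAO against Sham (1 split with as many, 4254 genes, highest other 3) and in MCAO+AS-exos against MCAO (1 split, 666 genes, highest other 308). It is not excluded for MCAO+Ctrl-exos against MCAO (2 splits, 8 genes, highest other 8) or MCAO+AS-exos against MCAO+Ctrl-exos (5 splits, 31 genes, highest other 340). The split with 340 genes parts MCAO+AS-exos replicates 1 to 3 and MCAO+Ctrl-exos replicate 3 from the rest, which points to a structure of the samples, the closeness of those 3 replicates. The other splits with as many also keep these 3 together, as do those with 308, 306 and 186 genes in MCAO+AS-exos against MCAO, where no other split gave more than 1. The exclusion of chance for the 666 genes thus holds only if these 3 libraries are independent, and without replicate 1, 2 or 3 the count was 2, 0 and 0. For gene lists, chance is excluded for MCAO+Ctrl-exos against MCAO (1 split, 7 lists, highest other 6), but by 1 list only. Leaving out a library gave 2 to 5 lists, which other splits reach, and an estimated correlation 0, so this exclusion is weak. Chance is not excluded for MCAO against Sham (4 splits, 16 lists, highest other 17), MCAO+AS-exos against MCAO+Ctrl-exos (8 splits, 7 lists, highest other 10) or MCAO+AS-exos against MCAO (14 splits, 7 lists, highest other 11), nor for the correlation of the AS-exos and injury differences (8 splits, r = -0.103, highest other 0.136 in size). For MCAO against Sham the 3 other splits with 16 or 17 lists set 3 Sham libraries and 1 MCAO library against the rest and so carry part of the injury difference, while splits of 2 and 2 gave 0 to 5 lists.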

How the results depend on the processing

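Scaled totals, trend removal, trend removal with quantile normalization and the omission of MCAO+AS-exos replicate 4 with MCAO+Ctrl-exos replicate 1 were tests chosen after the data were seen. The gene count of MCAO against Sham stayed within 1.5 times 4254 under every alternative (3605 to 4248, and 3814 to 4251 with a library left out). For the others the cause was not tested unless stated. The gene counts that moved were, for MCAO+Ctrl-exos against MCAO (8), MCAO+AS-exos against MCAO+Ctrl-exos (31) and MCAO+AS-exos against MCAO (666) in that order, 59, 3266 and 3955 with quality weights, which gave MCAO+AS-exos replicates 1 to 3 weights of 2.93 to 6.27 and replicate 4 0.320. They were 3, 9 and 31 with only the 8 libraries compared, 3, 55 and 377 with trends removed, 4, 76 and 319 with quantile normalization as well, and 168, 1088 and 2155 with both libraries left out. For the first and the second of these comparisons, limma without trend gave 2 and 16, and the replicate block 5 and 68. Quantile normalization gave 88 and 318 for the second and the third. No filter gave 3 and scaled totals 5 for the first, and a minimum of 5 FPKM 93 for the second. Leaving out 1 library gave 2 to 89, 1 to 1297 and 0 to 2024. Lists that moved by camera (16 for MCAO against Sham and 7 for each other comparison, in the order above) were 8, 0, 0 and 0 with an estimated correlation, against 12, 3, 2 and 5 at an unadjusted p below 0.05. By fry they were 23 for MCAO against Sham and 0, 1 and 0 in the exosome comparisons, against 23, 6, 8 and 8 unadjusted. The mixed form of fry, which counts changes of members in either direction, called 26 lists for MCAO against Sham and 5, 21 and 18 in the exosome comparisons. It was not run on the splits. With quantile normalization 3 moved for MCAO+Ctrl-exos and 4 for MCAO+AS-exos against MCAO, and with trends removed 3 for the former. With a library left out they were 16 to 18, 2 to 5, 5 to 9 and 5 to 9, and with the replicate block 16, 5, 6 and 6. The correlation of both exosome effects, 0.492, was 0.155 with the MCAO libraries split between them, which by construction removes the shared libraries, and 0.434 to 0.565 with a library left out; the replicate block leaves it unchanged by construction. The correlation with the injury effect, -0.103, ranged from -0.125 to -0.0844 with a library left out. Named genes gave 7930 values under alternatives for 610 results: 7181 stayed on their side of the threshold, 597 no longer passed, 152 newly passed and 0 changed sign while called. Changes of sign in genes called in neither fit were not counted. Of the 597, 312 came from leaving out a library in MCAO+AS-exos against MCAO. Another 105 came from leaving out a library in MCAO+AS-exos against MCAO+Ctrl-exos. What depth limits cannot be given, as the files hold no counts.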

Other observations

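These values were looked at after the data were seen. The 10 most abundant genes held 27.5 to 30.6% of the FPKM total in Sham libraries and 13.3 to 19.1% in the others. The total was 784006 in MCAO+Ctrl-exos replicate 1 and 936101 to 983648 in replicates 2 to 4, whose transcripts under 1000 bases held 59.4 to 62.3% of it against 51.9% in replicate 1.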
